A study of Rattus norvegicus with 21 samples.

How the data were processed

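Single neurons were patched, recorded and aspirated, and their polyadenylated RNA was amplified with SMART-Seq v4, made into Nextera XT libraries and sequenced as read pairs on a NextSeq500, per the labels' protocols. Molecular identifiers are not mentioned in the labels, so intervals and floors cover counting error only. STAR 2.4.0, FastQC, Picard, SAMtools, DESeq2 and the build rn6 are named in the submitters' processing notes. The read counter, the annotation and the strand setting are not given in the sources used here.

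The deposited values are a never-negative signal per gene that the authors name as DESeq2-normalized; how the factors were set is not given in the sources used here. The table has 34976 rows, of which 18376 have no gene symbol, and 0 columns of values lacked a sample. For 16245 symbols 1 row each was kept, the one with the highest mean, which left out 355 rows. Of these symbols 14112 are current in a rat gene table of assembly GRCr8 and 1739 are among its synonyms. That assembly differs from rn6, so it gave names only. The 14 rows of the mitochondrial chromosome have no symbol, so the list of mitochondrially encoded genes had 0 members and has no result.

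Each cell's values were whole multiples of 1 step, in 100% of values within 0.05 of a whole number, as for read counts divided by 1 factor per cell, which gave back whole reads and the depth per cell. A count test on these reads was not run: the labels name no animal or culture, each group is then 1 sample, and such a test would take cells for replicates.

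Per gene, the group mean of log2 of the normalized value plus 1 was taken over cells and the difference of 2 groups was computed over genes above 0 in at least 3 of their cells. These differences are on a log scale with a pseudocount and largely follow whether a gene was detected in a cell. Of 27 gene lists fixed before the data were examined, those with at least 3 measured members had their median difference placed among 10000 random lists matched on mean expression in 20 bins. A list was called apart in the outer 2.5% of random lists on either side, as a description of these libraries. In the 4 comparisons 86 such percentiles were computed, of which 19 were apart, 8 of them in the pyramidal comparison. Lists of unrelated genes in independent comparisons would give 4.3. Members of a list can vary together and the comparisons share groups, so the 2 numbers do not measure an excess over chance. Named genes came, per comparison and direction, from the 12 with the largest difference left after leaving out any 1 cell, among genes with a mean of at least 50 and values above 0 in at least 4 cells of the higher group. List members and identity genes fixed beforehand are named besides. The comparison of named genes with simulated no-effect groups was chosen after seeing the data.

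The scripts were tested on simulated cells with the detection rates, means and depths of the real ones and 200 genes changed 8-fold. With every gene detected, the differences came back as 3.04 and -3.00 for a true 3 and -3 in the pyramidal comparison. With real detection rates, the share of lists of 15 changed genes found apart was 5.00% for higher and 50.0% for lower genes in the pyramidal comparison, 27.5% and 50.0% for purified against glia-cultured cells, 100% and 82.5% for OCM-treated against purified cells, and 65.0% and 67.5% for OCM-treated against glia-cultured cells. Lists of unchanged genes were apart in 2.50%, 5.00%, 7.50% and 2.50% in the same order. Of 24 genes named in each simulation, 2, 1, 5 and 2 were truly changed. The simulated change moved a gene's level in cells where it was on and left its chance of being on unchanged. The naming rule largely follows detection, so these figures may not carry over to changes that alter detection. Outside OCM-treated against purified cells, a list that is not apart is therefore weak evidence of no difference. In that comparison the 100% and 82.5% concern 8-fold changes of all 15 members, and say nothing of smaller ones. A named gene alone is weak evidence of a difference.

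Alternatives fixed beforehand were pseudocounts of 10 and 0.1, scaling to one total or to one upper quartile, the ratio of group means, the median over cells, other filters on list members, leaving out each cell, cells of 1 title letter, thinning, and a split of the purified cells. Added after seeing the data were leaving out pyramidal cells 3 and 4, cells titled S for OCM-treated against glia-cultured neurons, scaling to the mean total, and a relation over genes above 0 in at least 14 of 16 cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.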

Results

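The contents of 21 single hippocampal neurons of Wistar rats carrying a Venus reporter for the vesicular GABA transporter were sequenced after patch-clamp recording. The neurons came from embryonic day 18 and had spent 17 days in vitro. They fall into 4 groups. There were 5 pyramidal and 6 GABAergic neurons from cultures that kept their glia. A further 5 GABAergic neurons came from cultures purified with an antimitotic agent, and 5 from purified cultures given medium conditioned by oligodendrocytes (OCM) from day 3 in vitro. The labels name no animal or culture for any neuron, so each group was treated as 1 sample: no p-value, standard error or number of changed genes is given, and SDs and ranges describe the spread between cells.

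Depth ran from 1817671 to 25160911 recovered reads per cell, and 2540 to 8652 genes, with or without a symbol, were above 0. After every cell was thinned to the smallest total, glia-cultured GABAergic neurons had 3609 to 8188 genes, purified ones 2539 to 3808, OCM-treated ones 3765 to 5683, and pyramidal neurons 2447 to 5006. Sample titles open with letters whose meaning is not given in the sources used here. Among glia-cultured GABAergic neurons, the 3 cells titled P had 5813 to 8188 genes after thinning, whereas the 2 titled ech had 3609 and 4503 and the 1 titled S had 4076. The other groups showed no such order: the 1 purified cell titled P had 2621, and pyramidal cells titled P had 2447 to 5006 against 2698 and 3913 for those titled S. All 5 OCM-treated cells and 4 of the 5 purified cells were titled S, so letter and group overlap.

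**Figure D1:**
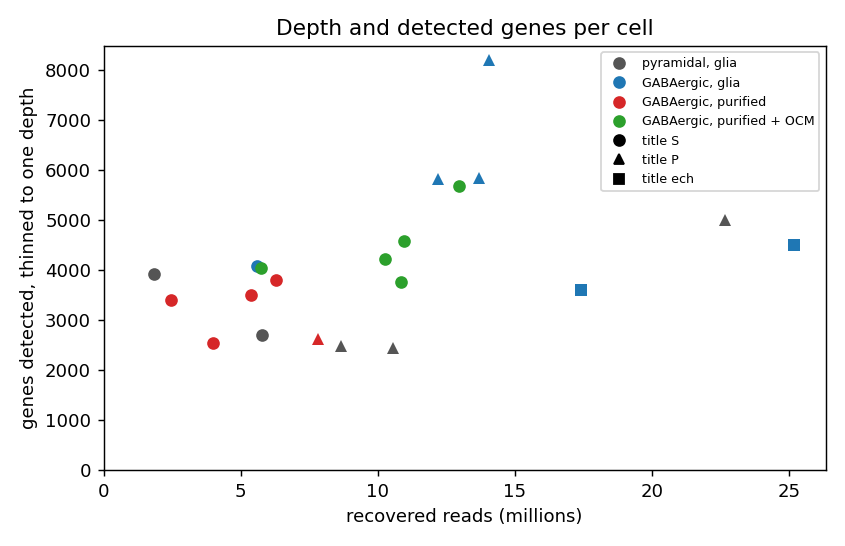
Genes detected in each cell after thinning to one depth, against recovered reads, with color for the group and shape for the title letters. The glia-cultured GABAergic cells titled P lie highest, at 5813 to 8188 genes, and the purified cells lie at 2539 to 3808.

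The first comparison asks how pyramidal neurons differed from GABAergic neurons in the same kind of culture. Gad1, which makes GABA (chromosome 3, 56861431 to 56902137 in rn6), had 0 reads in the 5 pyramidal cells and a mean normalized count of 14679 (SD 5411, 6 cells) in the GABAergic cells, at least 4148-fold lower in pyramidal cells. Slc17a7, the vesicular glutamate transporter (chromosome 1, 101161252 to 101173169), showed the opposite: a mean of 9785 (SD 6689) with counts in 4 of 5 pyramidal cells and 0 reads in all GABAergic cells of the series. Sgk1, a kinase gene, averaged 8724 (SD 7728) in pyramidal cells and had 0 reads in the glia-cultured GABAergic cells. These folds use a floor of 3 reads over the group.

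The median difference over 6571 measured genes was -2.05, so lists are read against matched random lists. All 8 measured GABAergic identity genes were lower in pyramidal cells, among them Gad2, and the list's median difference of log2 values was -9.34, below all 10000 random lists matched on expression (percentile 0). Of the 8 glutamatergic genes, 6 were higher, with Slc17a7 and Bhlhe22 highest and Slc30a3 and Camk2a lower, for a median of 4.21 (percentile 100). Activity-regulated genes had a median of 1.58 (percentile 100), 0.00 to 2.53 with any 1 cell left out, with 9 of 13 higher, Egr4 and Egr1 most and Vgf least. Both of the identity lists and the activity list stayed apart among cells titled P (medians -9.79, 0.72 and 0.53). The pyramidal cells titled P are cells 3, 4 and 5, of which 3 and 4 carried glial transcripts, described below. Without cells 3 and 4 the medians were -8.63, 3.43 and 1.54, and these lists stayed apart. The activity list was not apart with the median over cells (percentile 88.0). GABA receptor genes had a median of -4.65 (percentile 2.42), with Gabbr1 among the lowest, but stayed apart in only 4 of 11 settings with 1 cell left out and were not apart among cells titled P (percentile 18.6). The pan-neuronal list had a median of -2.88 (percentile 1.59), which became -1.72 (percentile 8.60) without pyramidal cells 3 and 4.

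Transcripts of other cell types accompanied this contrast. All 6 measured oligodendrocyte genes were higher in the pyramidal group (median 2.90, percentile 99.99), as were the 3 vascular and fibroblast genes (median 2.92, percentile 99.6), and the astrocyte list had a median of 0.38 (percentile 98.2), -1.41 to 0.80 with any 1 cell left out and apart in only 6 of 11 such settings. Most oligodendrocyte genes were high in 2 cells: Mbp, a myelin gene, was at 278859 in pyramidal cell 3 and 95386 in pyramidal cell 4 and at 0 in the other 3, whereas Olig2 was at 1604 in pyramidal cell 2. Pyramidal cell 3 also had Apoe at 59681 and no Slc17a7 reads. Without cells 3 and 4 the oligodendrocyte median was -1.67 (percentile 52.9), the astrocyte list was at percentile 66.6 and the vascular list at 98.3. With all cells and no filter on members the vascular list was at 50. Its median was 0 there, so that setting cannot show whether the list is apart.

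Genes named by the fixed rule as higher in pyramidal cells included Sgk1, Slc17a7, Cd24, Mal2, Spata2L, Ccsap, Fars2, Hpca, Ctxn1, Mphosph8 // Parp4 and Nasp. Those named as lower included Gad1, Spock3, Dner, Csdc2, Cntnap4, Uba1, Glrb, Vstm2a, Sv2a, Nap1l5 and Pnoc. In 100 simulated comparisons of these cells with no gene changed, on/off detection and simulated variation in level gave top genes of up to 9.11 higher and -12.51 lower (95th percentile of draws). Only Sgk1 (11.23), Slc17a7 (9.97) and Gad1 (-13.62) lay beyond that range. The simulation drew detection at each gene's rate over both groups together, so real differences in detection would widen the range. That rate was scaled by the detection rate of each cell. A difference between groups in the number of detected genes is thus part of the no-effect range. The range is also that of the largest gene in each draw. A gene within it is therefore not told apart from simulated noise here, but is not shown to be noise. The same limits hold for the ranges of the later comparisons.

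**Figure D2:**
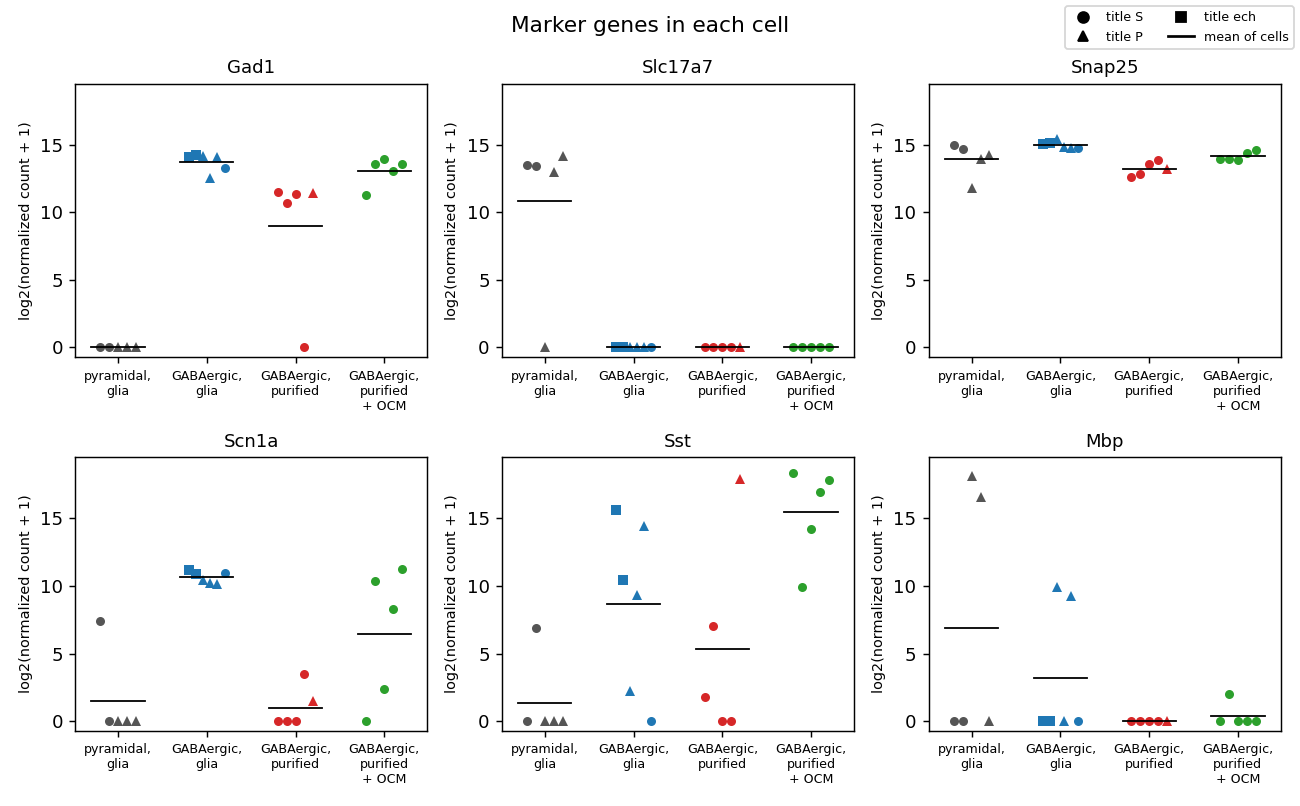
Log2 of the normalized count plus 1 of 6 genes in each cell, by group, with shapes for title letters and bars for the mean of cells. Gad1 is at 0 in all 5 pyramidal cells, Slc17a7 is above 0 in 4 pyramidal cells and in no other cell, and Mbp is at its highest in pyramidal cells 3 and 4.

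The next comparison asks what differed in GABAergic neurons grown without glia. The cultures with glia had no antimitotic agent, so the design cannot separate its action from the absence of glia. Gad1 averaged 1973 (SD 1209, 5 cells) in purified cells against 14679 (SD 5411, 6 cells) with glia, and Snap25, a synaptic vesicle fusion gene, averaged 9797 (SD 3427) against 32974 (SD 6442), with no overlap between cells for either. Scn1a, a sodium channel gene, averaged 2.44 in purified cells and 1644 with glia, where its lowest cell was at 1157. Slc32a1, the vesicular GABA transporter, was similar, at 713 (SD 383) and 629 (SD 269). Reln was higher in purified cells, at 6463 (SD 4250) against 566 (SD 936). These groups also held different subtype transcripts. Cck was at 19464 and 28143 in purified cells 1 and 2 and at 0 in the other purified cells. In glia-cultured GABAergic cells it was at 187 or less. Whether the mix of subtypes bears on such differences was not tested.

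The median over 6302 measured genes was -2.13, so lists are read against matched random lists. Cholesterol synthesis genes stood above them, with a median of 0.92 (percentile 100), 0.03 to 1.83 with any 1 cell left out. Of 15 genes 9 were higher, Cyp51 and Fdft1 most, and Hmgcs1 was lower. Single cells overlapped and followed the title letters. The score (mean log2 value over members) was 8.87 and 8.48 in glia-cultured cells 3 and 5, titled P. Both lay above the purified range of 5.66 to 7.75. Glia-cultured cell 4, also titled P, had 6.26, and those titled ech or S had 3.59 to 4.10. Cytosolic ribosomal protein genes had a median of 0.13 (percentile 99.3), -0.19 to 0.72 with any 1 cell left out, so without a direction of their own. GABA receptor genes had a median of -4.70 (percentile 1.72), with 11 of 12 lower, Gabra5 among the lowest, but stayed apart in only 5 of 11 settings with 1 cell left out and were at 29.8 with the median over cells. All 16 presynaptic release genes were lower (median -2.47, percentile 2.84), Vamp1 most, and glutamate receptor genes had a median of -4.43 (percentile 2.63), though neither list passed the 2.5th percentile. Sodium channel genes (median -3.48, percentile 16.5) and GABAergic identity genes (median -2.54, percentile 8.21) were not apart from matched genes. All 7 measured astrocyte genes were lower in purified cells (median -2.43, percentile 22.3), also not apart.

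Rows without a symbol took 23.0% of the values on average in purified cells and 16.2% in glia-cultured ones, and the most abundant row averaged 9.73% and 5.14%. The all-gene median depended on which glia-cultured cells were used. Against each of the 3 cells titled P it was -2.71, -2.75 and -4.34, and against 1 titled ech it was -0.88. Against the other titled ech and the 1 titled S it was 0, a value set by genes at 0 on both sides. With cells titled S alone, 4 against 1, which cannot show whether a list holds within a letter, cholesterol synthesis genes had a median of 1.76 (percentile 99.9), GABA receptor genes were at percentile 6.32 and ribosomal protein genes at 88.2.

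Named as higher in purified cells were Snx7, Tmem254, Cyp51, Iah1, Arf2, Idh1, Clasp1, Ibtk, Reln, Maged2, Lrrc41 and Dhcr7, and as lower Madd, Tmed7, Atl1, Pak1, Lrrn3, Rangap1, Gphn, Tmf1, Syt4, Trim9, Slc30a3 and Nop16. None of these 24 lay beyond the simulated no-effect range of 9.19 higher and -12.79 lower. That range includes the lower detection of purified cells, so it cannot decide on a broad loss of transcripts in them.

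The comparison named in the study's title sets purified GABAergic neurons with OCM beside those without. The median over 5143 measured genes was 1.40, so list medians and counts of higher members are read against matched random lists. Activity-regulated genes were higher in OCM-treated cells for all 8 measured members, with a median of 4.91 (percentile 99.99) that stayed between 4.45 and 5.20 when any 1 cell was left out, and at 4.63 among cells titled S. With no filter on members the median was 1.69 and the list was not apart (percentile 97.0). Egr4 and Fos differed most, Vgf and Nr4a2 least. Fos averaged 3314 (SD 3890) in OCM-treated cells, the lowest at 574, and 631 (SD 1329) in purified cells, where 2 of 5 were at 0. Gad1 averaged 10160 (SD 4978) against 1973 (SD 1209), and Snap25 18422 (SD 4524) against 9797 (SD 3427). The lists that hold Snap25 were not apart. Presynaptic release genes were higher for 11 of 16 (median 0.84, percentile 60.4) and pan-neuronal genes for 10 of 17 (median 0.52, percentile 79.7). GABA receptor genes were higher for 6 of 9 (percentile 63.8), also not apart.

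Nuclear oxidative phosphorylation genes were higher for all 16 measured members, with a small median of 0.65 (percentile 97.9). Random lists matched on expression had 0.18. The list stayed apart in 7 of 10 settings with 1 cell left out. It was not apart among cells titled S (percentile 96.3) or with no filter on members (78.5). GABAergic identity genes were higher for 8 of 9 (median 2.58, percentile 97.2), Sp9 and Gad1 most, and were not apart. All 6 sodium channel genes were higher (median 1.60, 0.61 to 2.63 with any 1 cell left out), but at percentile 56.4 this did not differ from matched genes, whose median was 1.39. Scn1a was above 0 in 4 of 5 OCM-treated cells and Scn2a averaged 3735 (SD 702) against 2695 (SD 1771).

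Interneuron subtype genes went both ways (median -0.66, percentile 0.92, and -1.41 to 0.57 with any 1 cell left out), Sst and Npy being highest and Penk and Reln lowest, and were at percentile 7.36 among cells titled S. Sst, the somatostatin gene, was at 966 to 325053 in the 5 OCM-treated cells and at 0, 0, 2.47, 130 and 243977 in the purified cells. Npy was at 7270 or more in every OCM-treated cell and above 0 in 2 purified cells. Cck had 0 reads in the OCM-treated cells and was above 0 in 2 purified cells. The 2 groups thus hold cells with different subtype transcripts.

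Genes named as higher with OCM included Kdelr2, Mpp6, Gadd45g, Slc30a3, Nefh, Kcnip1, Kcnk3, Nans, Dcun1d4, Pigs, Sst and Igfbp4, and as lower Commd8, Nell2, Ankrd16, Gnai2, Clasp1, Nub1, Sirt3, Tfam, Zc3h14, Rad21 and Gdap1. None lay beyond the simulated no-effect range, which reached -10.11 among lower genes and further among higher ones.

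**Figure D3:**
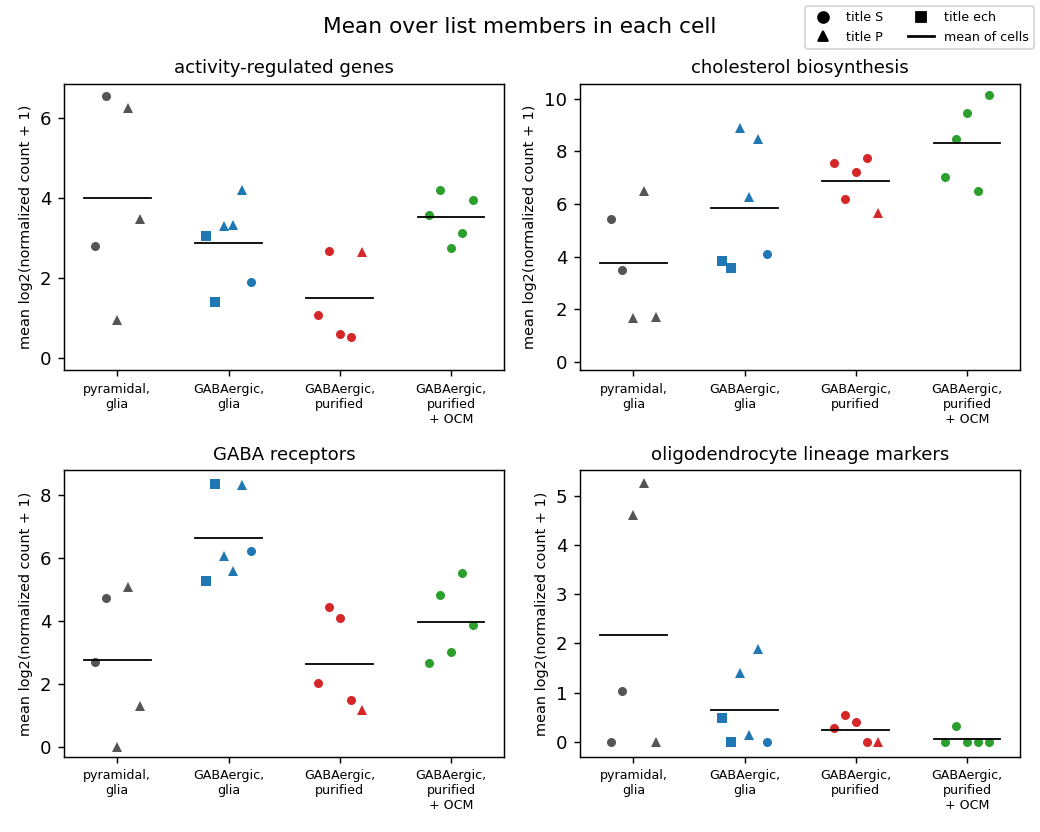
Mean log2 of the normalized count plus 1 over the members of 4 gene lists in each cell, by group, with bars for the mean of cells and shapes for title letters. The activity-regulated list is at 2.76 or more in OCM-treated cells and at 2.68 or less in purified cells.

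The last comparison sets OCM-treated purified neurons beside glia-cultured GABAergic neurons, which also differ in the antimitotic agent. The median over 6772 measured genes was -0.72. Cholesterol synthesis genes were higher in OCM-treated cells for 14 of 17 (median 2.33, percentile 100), Cyp51 and Mvd most, and Insig1 lower. Glia-cultured cells 3 and 5, titled P, had scores of 8.87 and 8.48, within the OCM-treated range of 6.47 to 10.1. Cyp51 averaged 2833 (SD 2696) against 360 (SD 483). Activity-regulated genes were higher for 8 of 10 (percentile 99.9), with Egr1 and Egr4 highest and Junb and Vgf lower, but were not apart with the median over cells (75.5), no filter on members (95.2) or the ratio of means (96.0). GABA receptor genes were lower for 11 of 12 (median -3.15, percentile 0.37), Gabra5 and Gabra2 most. They stayed apart in 9 of 11 settings with 1 cell left out. Synaptic adhesion and scaffold genes had a median of -2.42 (percentile 1.22), Dlg2 and Lrrtm2 lowest, and stayed apart in 6 of 11 such settings. Ribosomal protein genes had a median of 0.75 (percentile 99.5), 0.12 to 0.90 with any 1 cell left out. This list stayed apart in 9 of 11 such settings and was not apart with the ratio of means (percentile 94.9). Gad1 averaged 10160 and 14679, with overlapping cells. All 8 measured astrocyte genes were lower in OCM-treated cells (median -1.59, percentile 10.9), but were not apart.

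Against the 1 glia-cultured cell titled S, medians were 4.14 for cholesterol synthesis, 2.85 for activity-regulated and -4.36 for GABA receptor genes, and adhesion genes were at percentile 0.36 and ribosomal protein genes at 64.9. These values describe that 1 cell and cannot show whether a list holds within a letter. Genes named as higher included Cd320, Ackr3, Ddah2, Samm50, Npy, Tmem254, Egr1, Idh1, Supt16h, Tmem248, Kcnk3 and Ccne1, and as lower Nrsn1, Mfn2, Dlg2, Wdfy1, Pdk2, Nfs1, Nub1, Slitrk4, Pde1b, Mrpl50 and Foxj3. None lay beyond the simulated no-effect range of 9.46 higher and -10.78 lower.

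**Figure D4:**
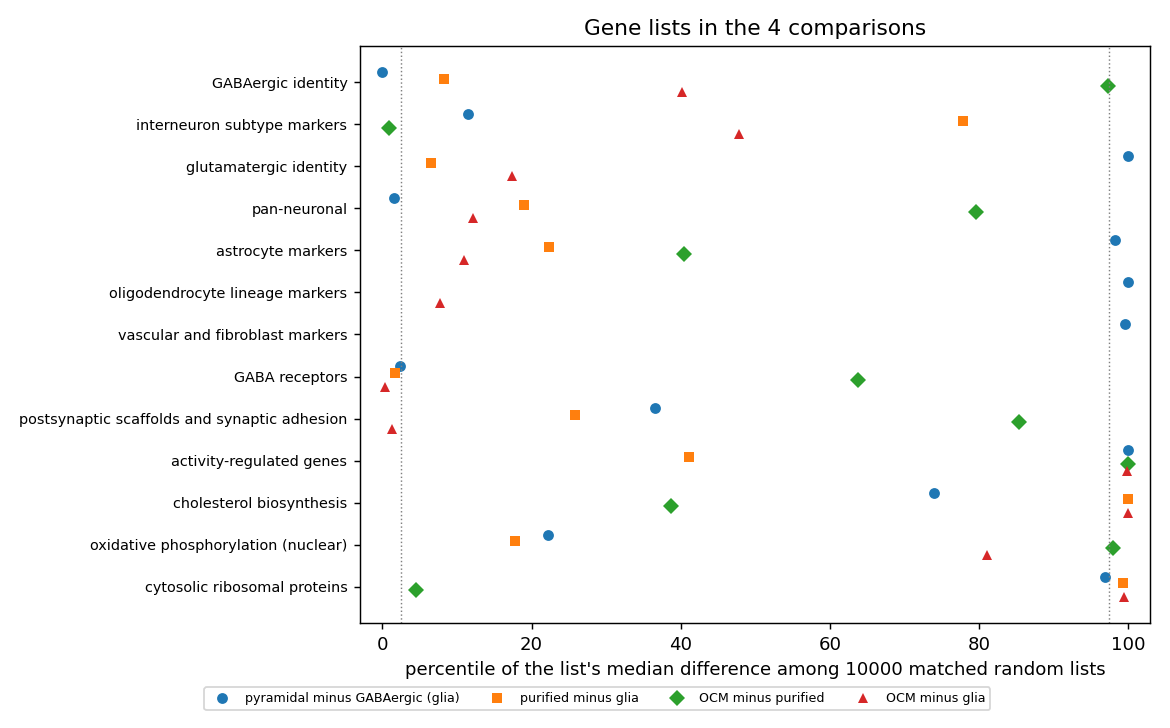
Percentile of each list's median difference among 10000 random lists matched on expression, for the lists apart in at least 1 of the 4 comparisons, with dotted lines at the limits for a list apart. Cholesterol synthesis lies at 100 for purified and for OCM-treated against glia-cultured GABAergic cells and at 73.9 for pyramidal cells, and activity-regulated genes at 99.99 with OCM.

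Differences with OCM and with glia were set side by side across 7305 genes. The difference OCM minus purified correlated with the difference glia-cultured minus purified at r = 0.58 across genes, which are not independent replicates. Unchanged groups sharing the purified cells gave a mean r of 0.54 in 100 simulations (-0.0038 to 0.89). With the purified cells split so that no cell served both differences, r was 0.089 on average over 20 splits (0.062 to 0.10). The covariance was 3.87 against 3.02 in the simulations, a difference of 0.85, and 0.87 with split cells. Over the 1144 genes above 0 in at least 14 of 16 cells, a choice made after seeing the data, r was 0.76, 0.54 in the simulations (-0.31 to 0.93) and 0.046 with split cells. There the covariance exceeded the simulated one by 1.40 and was 0.28 with split cells, so the 2 ways of allowing for the shared cells gave different values. The simulations drew on the spread of all 16 cells, whereas the shared part depends on that of the purified cells alone. The excess over the simulations therefore does not measure a shared difference.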

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

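All tests of explanations below were chosen after the results were seen. In 68 checks of 17 measures over 4 groups, 4 scores, in 2 cells, passed a rule for a value apart from the others of its group. The rule's nominal rate would give 3.4. Where the others are all 0, any value above 0 passes, so that rate does not hold here. OCM-treated cell 2 had a score (mean log2 value) of 2.56 for glutamatergic identity genes (others 0.62 to 1.04), of 0.33 for oligodendrocyte genes (others 0) and of 1.55 for vascular and fibroblast genes (others 0). That cell also had the most genes of its group after thinning, 5683 (others 3765 to 4574), and scores rise with the genes detected. Its glutamatergic share of values was 0.015%, within the 0.0061 to 0.088% of the others. Purified cell 3 had a score of 0.40 for vascular and fibroblast genes (others 0). Rows without a gene symbol, which entered the genes detected but no comparison of genes or lists, held much signal. The most abundant one, on chromosome 14 from 46643222 to 46655563, took 32.4% of the values of pyramidal cell 3 (3.05 to 18.4% elsewhere), and the unnamed mitochondrial rows took 20.9% in pyramidal cell 2 (1.25 to 10.8% elsewhere).

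Myelin transcripts marked pyramidal cells 3 and 4. Cell 4 kept a pan-neuronal share of 1.19% of its values, within that of the other pyramidal cells, and had Slc17a7, so RNA of another cell taken up beside the neuron's own is a candidate explanation there. Cell 3 had a pan-neuronal share of 0.156%, or 0.238 of the lowest of cells 1, 2 and 5. It had 0 GABA and 0 glutamate receptor genes, a microglia score of 6.55 and a proliferation score of 3.65, with Aurkb at 5202, but Snap25 at 3590. A neuron with much foreign RNA and another cell in place of a neuron both stay open. No biological explanation was tested.

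Purified cells had fewer genes than glia-cultured ones. Fewer reads were not the cause, since the ratio of mean genes was 0.595 with all reads and 0.595 after thinning. A difference tied to the title letters stays open: among cells titled S the ratio was 0.814, with only 1 such glia-cultured cell, and among cells titled P it was 0.396, with only 1 such purified cell, so neither decides. The absence of glia, which the design names, also stays open. Glial RNA taken up with the glia-cultured neurons was not tested. Astrocyte scores were 3.05 to 4.70 in glia-cultured GABAergic cells titled P and 1.63 to 1.71 in those titled ech or S. Such scores also rise with the genes detected, so these values do not decide. The antimitotic agent was given to the purified and OCM-treated cultures only, so its own action cannot be told apart from the absence of glia.

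Activity-regulated genes were higher with OCM than without. More detected genes in OCM-treated cells stay open as an explanation: the list lay at percentile 99.99 among lists matched on expression, but at 97.0 with no filter on members, where it was not apart. Another mix of interneuron subtypes stays open: purified cell 5, the one purified cell with Sst at the level of OCM-treated cells, had a score of 2.65 beside 2.76 or more in OCM-treated cells, but purified cell 2, with Cck and little Sst, had 2.68, and 1 cell of that subtype does not decide. An effect of OCM, which the design names, stays open as well.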

How the results depend on the processing

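GABAergic identity and glutamatergic identity in pyramidal cells stayed apart under every alternative run for lists. So did cholesterol synthesis in purified and in OCM-treated against glia-cultured GABAergic cells, though single cells overlapped there. Thinning and the split of the purified cells were not run for lists. Percentiles of the other lists apart moved as below; the cause was not tested unless the setting itself shows it. Some lists had a median of 0, set largely by values of 0, so their percentiles there decide little. With no filter these were the vascular and subtype lists. With the median over cells they were subtype, astrocyte and oligodendrocyte genes, and activity-regulated genes in pyramidal and in OCM-treated against glia-cultured GABAergic cells.

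In pyramidal cells, the astrocyte list was at percentile 96.5 with a pseudocount of 0.1, 97.49 scaled to the mean total (an added choice), 81.1 with the median over cells, 97.1 for members with a mean of at least 50, 66.6 without cells 3 and 4, and 42.9 to 99.4 leaving out 1 cell, lowest without pyramidal cell 3. GABA receptors were at 3.21 with that pseudocount, 17.9 with the median over cells, 18.6 for titles P, 15.4 without cells 3 and 4, and 0.50 to 9.54 leaving out 1 cell. Oligodendrocyte genes were at 94.8 with the median over cells and 52.9 without cells 3 and 4, where the Mbp difference turned from positive to -3.19. Activity-regulated genes were at 88.0 with the median over cells. The pan-neuronal list was at 19.9 with no filter on members, 8.60 without cells 3 and 4, and 0.06 to 12.3 leaving out 1 cell. Vascular genes were at 50 with no filter.

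For purified against glia-cultured cells, GABA receptors were at 4.80 with the ratio of means, 29.8 with the median over cells, 6.32 for titles S, and 0.25 to 8.12 leaving out 1 cell. Ribosomal protein genes were at 96.2 with the median over cells, 88.2 for titles S, and 97.0 to 99.97 leaving out 1 cell. The Scn2a difference, negative in the main setting, was 0.19 with the ratio of means, 0.53 with the median over cells, and -1.37 to 0.99 leaving out 1 cell. Sst, also negative in the main setting, turned to 1.99 with the ratio of means and 2.21 for titles S. Slc32a1, positive in the main setting, was -0.11 with the median over cells, -0.45 for titles S, and -0.12 to 0.40 leaving out 1 cell.

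For OCM-treated against purified cells, oxidative phosphorylation was at 97.1 scaled to one total, 78.5 with no filter, 96.3 for titles S, and 94.9 to 99.7 leaving out 1 cell. Subtype genes were at 6.56 with the ratio of means, 20.4 with the median over cells, 31.1 with no filter, 7.36 for titles S, and 0.28 to 21.8 leaving out 1 cell. Activity-regulated genes were at 97.0 with no filter.

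For OCM-treated against glia-cultured cells, adhesion genes were at 4.01 with a pseudocount of 0.1, 7.00 with the median over cells, and 0.43 to 17.8 leaving out 1 cell. Activity-regulated genes were at 96.0 with the ratio of means, 75.5 with the median over cells and 95.2 with no filter. Ribosomal protein genes were at 94.9 with the ratio of means, 64.9 for titles S (added), and 88.3 to 99.7 leaving out 1 cell. GABA receptors were at 0.13 to 7.63 leaving out 1 cell. The Slc32a1 difference, negative in the main setting, was 0.16 with the ratio of means and -0.84 to 0.17 leaving out 1 cell. For titles S, Scn2a turned from a positive main difference to -0.28 and Scn8a from a negative one to 3.81. Across genes, r was 0.089 with purified cells split.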

Other observations

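Interneuron subtype transcripts differed between single cells within groups. Cck was at 19464 and 28143 in purified cells 1 and 2 and at 0 in the other 3, and Cnr1, the cannabinoid receptor gene, was at 38420 and 14967 in the same cells. Penk was at 21284 in purified cell 1 and 25005 in purified cell 4. Reln was at 4608 or more in purified cells 1 to 4 and at 244 in purified cell 5, the cell with Sst at 243977. Pvalb had 0 reads in the OCM-treated cells and was above 0 in 2 glia-cultured GABAergic cells.

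Pyramidal cell 3 had Aif1 at 12526 and Cd68 at 15290, genes of microglia.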
